A study of Sus scrofa with 20 samples.

How the data were processed

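Backfat, the fat layer under the skin of the back, was sampled from 20 Italian Large White pigs, 10 females and 10 castrated males, one library per animal. Per the labels, the animals were kept together on the same diet, reached 150 to 160 kg and were slaughtered at 233 to 250 days of age, and the tissue was frozen in liquid nitrogen. Polyadenylated RNA was sequenced as paired 100 bp reads. Libraries are named here by labelled sex and a number that follows the order of the deposited samples and pairs no animals.

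The submitters' processing notes name TopHat2 2.0.8, Bowtie2 2.1.0.0, Cufflinks 2.1.1, DESeq2 and the pig genome build Sscrofa10.2, without giving the role of each. The annotation release, the strand setting, the counting tool and the handling of reads with several matches are not given in the sources used here. The authors deposited 1 table of raw read counts for 23483 Cufflinks loci, checked here to hold whole numbers. The authors also deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for the same loci and FPKM for 63418 isoforms. A locus is a Cufflinks transcription unit, and 12707 loci carried an Ensembl gene identifier. Gene symbols were matched by Ensembl identifier to a table of gene names, which named 9360 loci, and older list symbols were matched through the synonyms of a RefSeq table of Sscrofa11.1. LEP, ADIPOQ, FABP4, LPL, PLIN1 and XIST found no locus that way, and 474 loci spanned 2 or more Ensembl identifiers. Isoforms were tied to loci by matching sums of isoform FPKM to locus FPKM.

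Total counts ran from 25754778 to 51248122 per library with a median of 36922247, so a locus at 1 CPM (counts scaled to library size) rested on 25.8 to 51.2 counts per library. No 2 of the 190 pairs of libraries had identical counts. Each of the 20 libraries' counts correlated best with its own FPKM column.

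Counts were tested with edgeR 4.0.16 quasi-likelihood fits (R 4.3.3), with TMM factors, the filterByExpr filter by group, which kept 21587 loci, and Benjamini-Hochberg adjustment at 0.05. The fits compared females with castrated males, estimated the slope on age with sex in the model, and tested the difference of age slopes between the sexes. All log2 differences between the sexes are females minus castrated males, and slopes are per 10 days of age. CPM are TMM-scaled, and log2 CPM used a prior count of 2. Lists of genes fixed in advance were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, where at least 5 members were tested. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way. Of 34 lists, 27 had enough members. The lists covered fat synthesis, storage, breakdown and oxidation, cholesterol synthesis, adipocyte factors, insulin signalling, steroid and estrogen genes, X-linked and Y-linked genes, markers of other cell types, immune genes, the clock, proliferation, brown fat, stress genes and mitochondrial genes.

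Isoforms were tested by limma-trend on log2(FPKM + 0.1) where FPKM was at least 0.5 in 10 libraries, which kept 33316 isoforms. Isoform shares were tested by limma on the arcsine square root of the share of the locus FPKM, for 18417 isoforms of 7290 loci with summed FPKM of at least 1 in all libraries and a mean share of 10 to 90%. Covariation of a list was the mean pairwise Pearson correlation of its members over log2 CPM with sex means removed, set against 10000 random lists matched on expression, and a list was called where it exceeded the bound passed by 2.5% of them. A library's list score was the mean of its members' z-scores. The fatty acid synthesis score was correlated with 26 other scores, with members shared by both left out, 100000 permutations, two-sided, and Benjamini-Hochberg adjustment over the 26. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for these steps. The gene, isoform and share fits were tested on simulated data of the same size with planted changes, with levels and spread taken from the real libraries. Values varied independently there and planted sex differences followed the label of every library. These runs cannot show recovery with correlated genes or with libraries that disagree with their labels. The list test was tried on simulated independent genes, which cannot show how it behaves with correlated members. The covariation step was tried on a smaller simulated set of genes.

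The comparisons, the lists, the rule for named genes and most alternative settings were chosen before the data were examined. The rule for named genes took, per comparison, up to 12 genes with a symbol per direction past the threshold and up to 4 members per list past it. It also took, whatever their result, the genes known from adipose tissue. Where fewer than 5 passed in a direction, it took the 5 of smallest p as values. For abundance it took the 10 loci of highest mean CPM and the 10 of highest spread among loci of mean CPM of at least 10. Loci without a symbol were chosen for naming after their values were seen.

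Alternatives to the edgeR fits were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 10 libraries, DESeq2 1.42.0, limma-voom with quality weights, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1, the 10 highest loci left out, age or a muscle marker score added, sex left out of the age fit, and each library left out in turn. After the data were seen, fits without the 2 libraries numbered 10 were added, with DESeq2 and an estimated correlation beside them, because those libraries' sex-linked loci disagreed with their labels. Samples were never relabelled. A planned test of the chromosomes of sex-differing genes was left out, since the chromosomes given here were those of Sscrofa11.1, another build than that of the loci, and that table was used for names alone. Samples were grouped by labelled sex alone, since the labels give no measure of fatness.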

Results

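The data were read counts and FPKM of polyadenylated RNA in backfat from 10 female and 10 castrated male pigs, and describe which genes this fat layer expressed, how it differed between the sexes and with age at slaughter, and how it varied between animals. Ages averaged 244 ± 5.64 days in females and 240 ± 4.53 days in castrated males (SD, n = 10 each), a difference of 3.9 days with a two-sided permutation p = 0.114. Total counts averaged 37250096 ± 7044959 in females and 36863736 ± 4229869 in castrated males (permutation p = 0.884). The library labelled female 10 had the lowest total, 25754778, the library labelled castrated male 10 had 28009303, and female 1 had the highest, 51248122. The other 17 libraries lay between 29281478 (female 9) and 43806528 (castrated male 6). Mitochondrial loci took 4.92% of counts in castrated male 1 and 16% in the library labelled castrated male 10, the lowest and highest shares.

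Backfat RNA was rich in transcripts of mitochondria, fat synthesis and matrix. The locus holding ATP8, ATP6 and COX3, mitochondrial subunits of ATP synthase and cytochrome oxidase, averaged 54620 ± 16560 CPM (SD, n = 20), and COX1 averaged 39580 ± 12920 CPM. SCD, the desaturase that makes oleate from stearate, was the highest nuclear gene with a symbol of its own at 15670 ± 7717 CPM. COL3A1, a fibrillar collagen, averaged 10420 ± 2390 CPM. The other 6 of the 10 most abundant loci were COX2, CYTB, ND5, the locus of ND4L and ND4, a locus spanning 2 gene identifiers of which 1 is CDH15, and a locus without a symbol. FASN, the fatty acid synthase, averaged 2154 ± 1403 CPM, LIPE, the hormone-sensitive lipase, 609 ± 192 CPM, PNPLA2, the triglyceride lipase of fat cells, 602 ± 120 CPM, and PPARG, the master regulator of fat cell differentiation, 303 ± 72.3 CPM.

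SCD and FASN were also among the loci that varied most between animals. SCD ran from 253 CPM in castrated male 1 to 28330 CPM in female 4, a 111.9-fold range, and FASN from 83.4 CPM in castrated male 1 to 4582 CPM in castrated male 3, a 55-fold range. The residual SD of log2 CPM with sex means removed was 1.58 for SCD and 1.56 for FASN, against a median of 0.262 over 8769 loci of mean CPM of at least 10. Without castrated male 1 the SD was 0.859 for SCD and 1.24 for FASN against a median of 0.255, and the ranges, from 2441 and 271.4 CPM in female 9, were 11.6-fold and 16.9-fold. Of the 10 loci of highest spread, CILP2, a cartilage matrix gene, was the sole one with a symbol, with a residual SD of 2.99 and CPM from 0.0268 in castrated male 8 to 30.7 in female 1. The loci that separated the sexes made up 5 of these 10, since the libraries numbered 10 broke their groups.

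**Figure D1:**
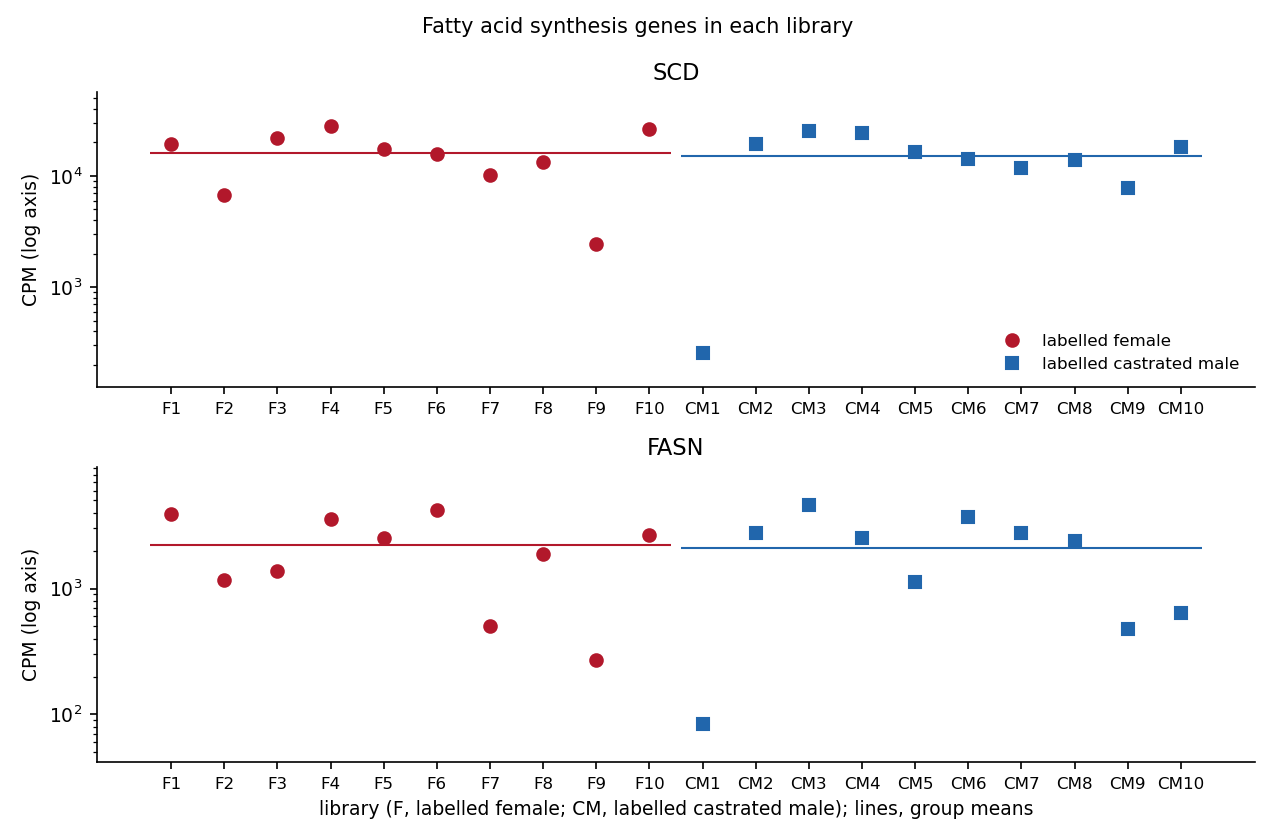
CPM of SCD and FASN in each library on a log axis, with horizontal lines at the mean of each labelled sex. Castrated male 1 is the lowest library for both genes, at 253 and 83.4 CPM, and female 9 the next lowest for both.

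Females and castrated males were compared to find genes that depend on sex or castration. With all 20 libraries as labelled, 0 of 21587 loci passed an adjusted p of 0.05 in edgeR, 935 had an unadjusted p under 0.05, and DESeq2 called 5, limma-voom with quality weights 9, and limma-trend on FPKM 9 or 11. The DESeq2 calls with a symbol were KDM6A, an X-linked histone demethylase with a Y copy, at +0.56 (adjusted p = 0.0371), and PRIM2, a primase subunit of DNA replication, at +0.77 (adjusted p = 0.0454). On simulated data of the same size 14.9% of DESeq2 calls were false, against 3.2% of edgeR calls. By the edgeR fit KDM6A stood at 60.3 ± 8.72 CPM in females and 41.0 ± 8.82 CPM in castrated males (SD, n = 10 each), a log2 difference of 0.56 with an SE of 0.112 and an adjusted p = 0.602.

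The libraries labelled female 10 and castrated male 10 carried the levels of the other sex at most of the loci that separated the remaining animals. Without those libraries 18 loci passed in edgeR (7 higher in females, 11 higher in castrated males) and 26 in DESeq2. XLOC_042132, a locus without a gene identifier, ran from 549 to 1224 CPM in 9 females and from 0 to 1.87 CPM in 9 castrated males (log2 difference 10.19, SE 0.555, adjusted p = 1.96e-10). It stood at 0.408 CPM in the library labelled female 10 and at 987 CPM in the library labelled castrated male 10. XLOC_042813, identifier ENSSSCG00000026430, ran from 226 to 325 CPM in 9 castrated males and from 0.020 to 1.31 CPM in 9 females (log2 difference -9.95, SE 0.50, adjusted p = 5.09e-11). It stood at 313 CPM in the library labelled female 10 and at 0 CPM in the library labelled castrated male 10, where a count of 0 allows up to 3 counts of 28009303. The named genes among the 18 were KDM6A, ENSSSCG00000012262, at 62.7 ± 5.61 against 38.5 ± 4.33 CPM (log2 difference 0.71, SE 0.075, adjusted p = 1.68e-05), and USP9X, an X-linked deubiquitinase with a Y copy, at 61.9 ± 4.53 against 47.5 ± 2.81 CPM (log2 difference 0.38, SE 0.059, adjusted p = 0.00366, n = 9 each). The USP9X locus spans 2 Ensembl identifiers. USP9X was an exception in the library labelled female 10, at 54.47 CPM within the 52.11 to 65.33 CPM of the 9 females. It stood at 75.95 CPM in the library labelled castrated male 10. In all, the library labelled female 10 lay on the castrated male side at 16 of the 18 loci and the library labelled castrated male 10 on the female side at 17. Of the Y-linked list 1 gene had a locus, AMELY, with 0 to 85 counts per library, and it did not pass the filter. All comparisons of the sexes that follow keep the labels as given, and the list tests and isoform counts also give values without the libraries numbered 10.

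**Figure D2:**
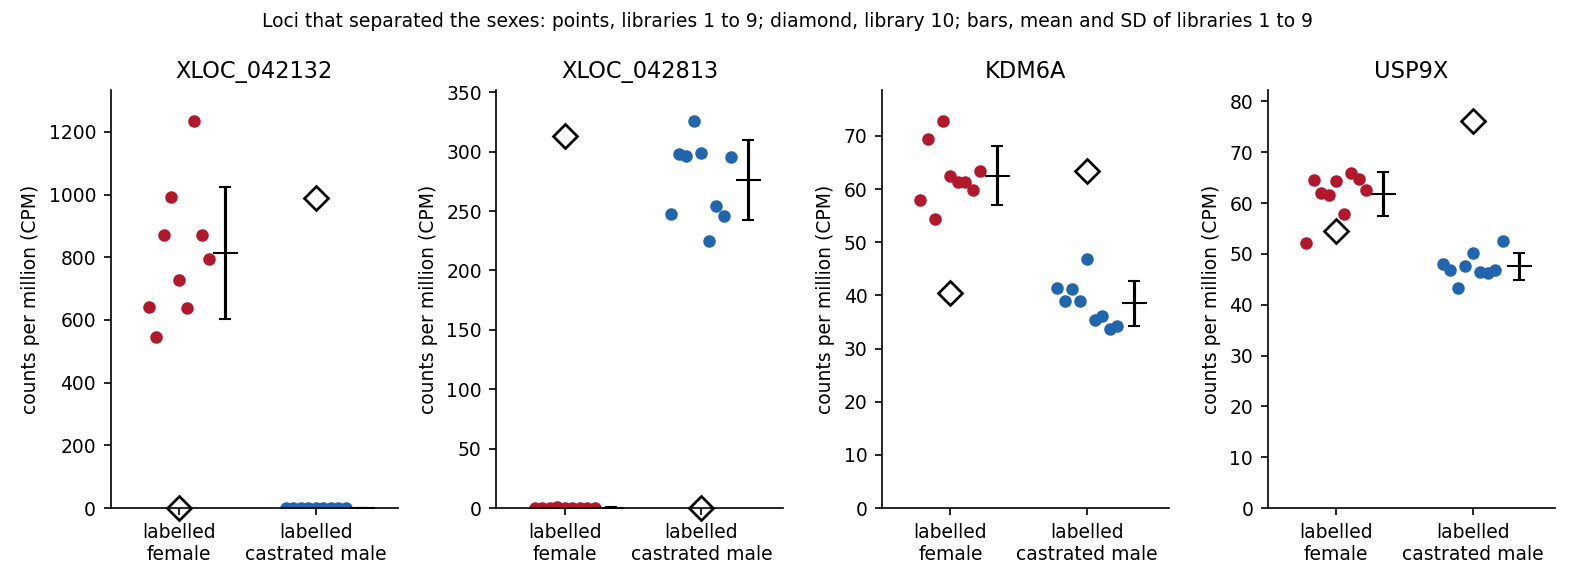
CPM of 2 loci without a symbol and of KDM6A and USP9X by labelled sex, with points for libraries 1 to 9 of each sex, bars for their mean and SD, and diamonds for the library numbered 10 of each sex. At XLOC_042132 and XLOC_042813 each diamond stands with the points of the other sex, as it does at KDM6A. At USP9X the diamond of the library labelled female 10, at 54.56 CPM, lies within the range of its labelled sex.

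Gene by gene, no named gene passed between the sexes in the edgeR fit of all 20 libraries, and those of smallest p are given as values. Above 0 after KDM6A and PRIM2 (18.8 ± 3.58 against 11 ± 3.61 CPM) came NAALAD2, whose symbol 2 loci bear, at +1.09 (SE 0.312), CUX2, a homeobox factor, at +0.56 (SE 0.167), and NDRG4 at +1.31 (SE 0.400), each with an adjusted p of 1. Below 0 came CTLA4, a T cell checkpoint receptor, at -1.50 (SE 0.444), CYTIP at -0.60 (SE 0.165), MYO1G at -0.65 (SE 0.191), PHF11 at -0.27 (SE 0.078), and the histone gene H2BC5 at -0.53 (SE 0.139), each with an adjusted p of 1. Adipose genes stood near 0: PPARG at -0.02 (SE 0.156), LIPE at -0.05 (SE 0.216), PNPLA2 at 0.00 (SE 0.141), SCD at +0.09 (SE 0.461) and FASN at +0.07 (SE 0.523). The signs of SCD, FASN, PPARG, PNPLA2 and LIPE turned under some alternatives, upper-quartile scaling included for PPARG and PNPLA2. On simulated data of the same size the edgeR fit recovered 47.8% of planted log2 differences of 0.58 and 79.1% of those of 1. There the changes followed the label of every library and genes varied independently. In the real fit XLOC_042132 did not pass, though it differed by a log2 of 10.19 without the libraries numbered 10. The simulated recovery therefore does not carry over to the fit of all 20 libraries.

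Immune gene lists were lower in females and matrix and vessel-wall lists higher, by list tests that held with a preset correlation and not with an estimated one. The preset calls are weak evidence of a sex difference. Of 100 groupings of the libraries, the real one included, 29 called 8 or more lists that way, and the others had a median of 5. T and NK cell markers fell with 13 of 14 members below 0 and a median of -0.55 (adjusted p = 8.26e-10 with the preset correlation, adjusted p = 0.314 with an estimated correlation): CD2 stood at 8.5 ± 3.41 against 13.4 ± 4.50 CPM, and CD8A at 5.25 ± 2.57 against 8.43 ± 3.35 CPM (SD, n = 10 each). Macrophage markers fell with all 11 members below 0 and a median of -0.65 (adjusted p = 2.84e-06; adjusted p = 0.429 with an estimated correlation): TYROBP, a myeloid adaptor, stood at 9.65 ± 3.65 against 16.6 ± 11.1 CPM and the scavenger receptor MSR1 at 16.3 ± 8.01 against 34.6 ± 34.6 CPM. Castrated male 1 was the highest library for MSR1 (115 CPM), LYZ (168 CPM) and C1QA (388 CPM). Inflammatory cytokines fell with 11 of 12 members below 0 (adjusted p = 0.00456; adjusted p = 0.429 with an estimated correlation), among them CCL3L1 at -0.99 and IL10 at -0.59. MHC class II genes fell with all 5 tested members below 0 (adjusted p = 0.0106; adjusted p = 0.507 with an estimated correlation), SLA-DMB at -0.46 and SLA-DQB1 at -0.32 among them. Interferon-stimulated genes fell with 12 of 13 below 0 (adjusted p = 0.0151; adjusted p = 0.680 with an estimated correlation), OAS2 at -0.72 and IFIT1 at -0.57 among them. No member of these 5 lists passed, adjusted over the list alone or over all genes.

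The fibroblast and matrix list rose in females with 15 of 16 members above 0 (adjusted p = 0.00561; adjusted p = 0.507 with an estimated correlation), with COL1A2 at 4185 ± 1048 against 3334 ± 852 CPM and COL5A1 at 443 ± 66.8 against 370.2 ± 112.4 CPM. Smooth muscle and pericyte markers rose with 6 of 8 above 0 (adjusted p = 0.00561; adjusted p = 0.429 with an estimated correlation), MYH11 at +0.49 and CNN1, a smooth muscle calponin, at +0.61 among them. X-linked genes with Y copies or known escape rose with 4 of 7 above 0 (adjusted p = 0.0145; adjusted p = 0.314 with an estimated correlation). Of them KDM6A and USP9X passed adjusted over the list alone and 0 over all genes. The other 19 lists did not pass, fatty acid synthesis (adjusted p = 0.762), triglyceride assembly (0.314), lipolysis (0.762), fatty acid uptake (0.974), fatty acid oxidation (0.974), cholesterol synthesis (0.881), steroid hormone genes (0.974), estrogen-responsive genes (0.762), adipokines and adipocyte factors (0.0867), insulin signalling (0.762), nerve markers (0.152), oxidative phosphorylation (0.307), immediate early and heat shock genes (0.0867), endothelial markers (0.762), proliferation (0.762), the circadian clock (0.321), brown or beige fat genes (0.760), mitochondrially encoded genes (0.762) and the reference adipose genes (0.762). Median, mean and test differed in sign for lipolysis, mitochondrially encoded, cholesterol and steroid genes. With an estimated correlation 0 of 27 lists passed (2 at an unadjusted p under 0.05), and with fry 0 (2 at an unadjusted p under 0.05).

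Calls of 4 lists rested on single libraries, and those of 4 lists did not hold with age in the model. With age added, the adjusted p was 0.294 for inflammatory cytokines, 0.0644 for MHC class II, 0.0837 for interferon-stimulated genes and 0.0644 for the X-linked list. The T and NK cell (adjusted p = 1.42e-06), macrophage (0.00500), matrix (0.000154) and smooth muscle (0.000302) lists passed with age added, and nerve markers joined them (0.0176, higher in females). These values used the preset correlation, and an estimated correlation was not run with age added. Without castrated male 1 the adjusted p was 0.158 for the X-linked list, 0.208 for MHC class II and 0.272 for interferon-stimulated genes. It was 0.0534 for MHC class II without female 2 and 0.0781 for the matrix list without female 3. For interferon-stimulated genes it was 0.0947 without female 3, 0.0592 without female 6, 0.0516 without castrated male 9 and 0.492 without the library labelled castrated male 10. Macrophage and T and NK cell lists passed in each of the 20 fits that left out 1 library. Without both libraries numbered 10 the count was again 8 lists, with interferon-stimulated genes out (adjusted p = 0.375) and immediate early and heat shock genes in (adjusted p = 0.00428, lower in females; adjusted p = 0.564 with an estimated correlation). Its heat shock members HSPH1, DNAJB1 and HSP90AA1 stood above 0 over all 20 libraries, at +1.05, +0.58 and +0.32. No other list changed sides.

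**Figure D3:**
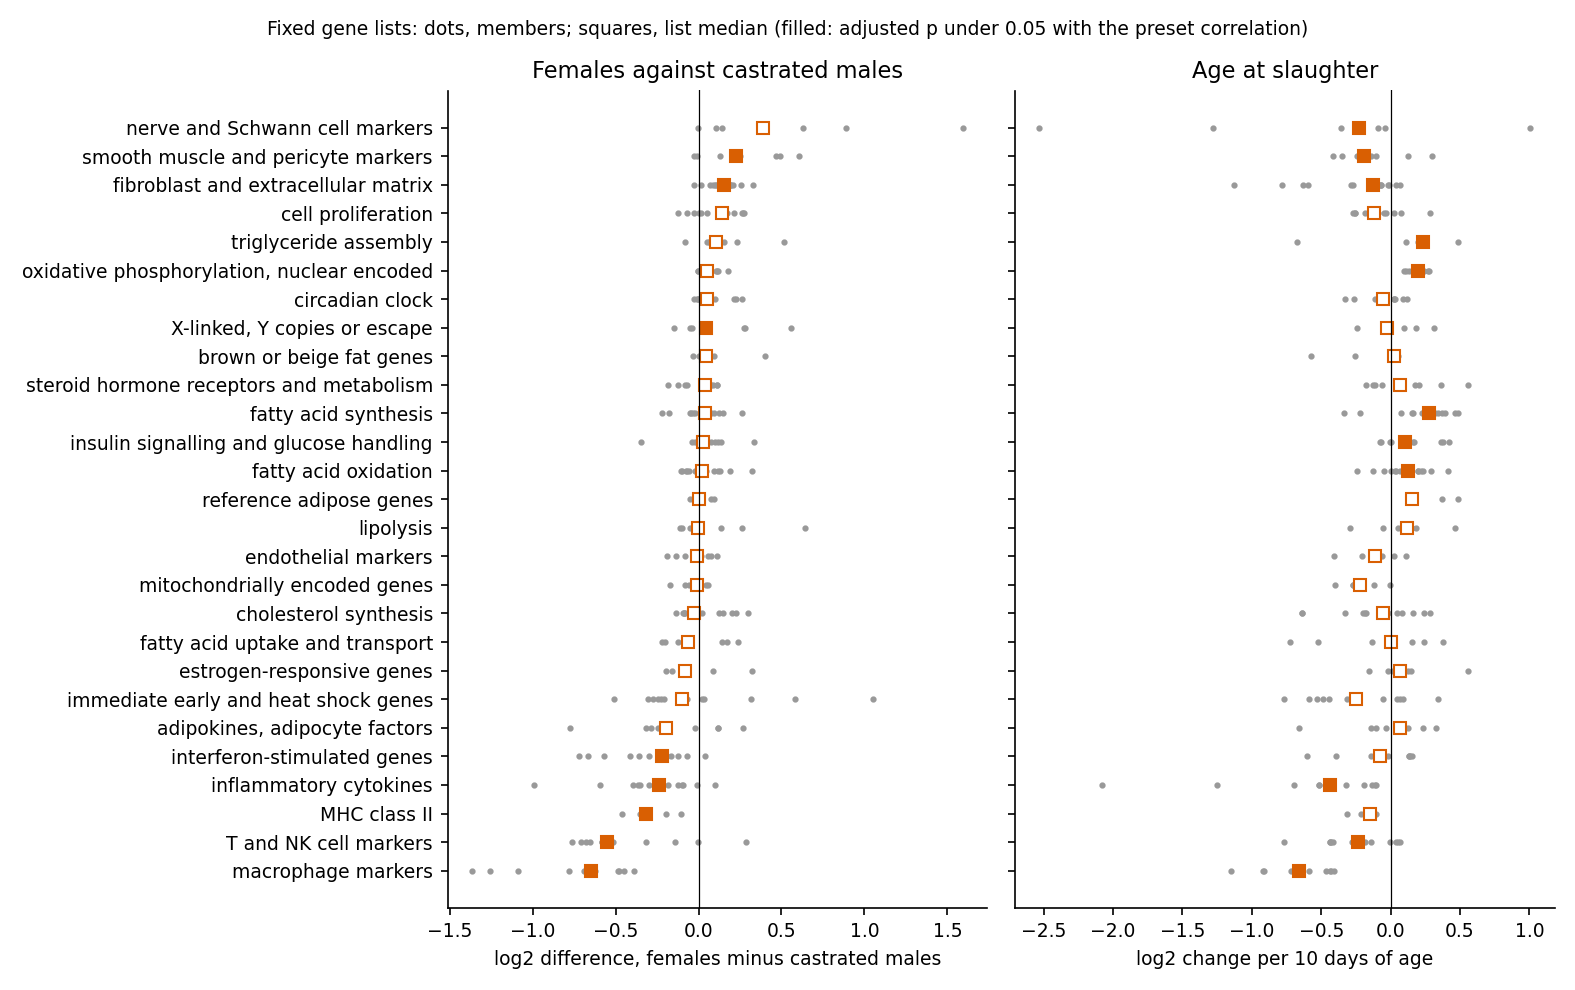
Log2 differences between the sexes (left) and log2 slopes per 10 days of age (right) for the members of each of 27 fixed gene lists as dots, with list medians as squares, filled where the list passed with the preset correlation. Macrophage markers have the lowest median in both panels, -0.65 and -0.66, and oxidative phosphorylation lies above 0 for all 14 members in the age panel.

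Age at slaughter, over a span of 233 to 250 days, was tested within sex for genes that differ between younger and older pigs of the same weight range. The labels give 150 to 160 kg for all animals and no single weights. Slopes on age therefore cannot be told apart from differences in growth rate or in weight within that range. In edgeR 0 of 21587 loci passed, with 1189 at an unadjusted p under 0.05, and DESeq2 called 6, limma-voom with quality weights 0 and limma-trend on FPKM 1, all without symbols. The genes of smallest p below 0 were TGFB3, a transforming growth factor, at -0.91 per 10 days (SE 0.198, adjusted p = 0.575), ADAMTS8, a matrix protease, at -1.19 (SE 0.261, adjusted p = 0.575), COL28A1, a minor collagen, at -1.25 (SE 0.299, adjusted p = 0.80), CARNS1 at -1.16 (SE 0.264) and BEST1 at -0.95 (SE 0.225). Above 0 stood SLITRK6 at +0.97 (SE 0.265), COL5A3 at +0.57 (SE 0.158), HOOK2 at +0.42 (SE 0.120), CTCFL at +1.15 (SE 0.368) and INTS12 at +0.29 (SE 0.096), with adjusted p from 0.848 to 0.859. Reference adipose genes had positive slopes that did not pass, FASN +0.48 (SE 0.570), SCD +0.37 (SE 0.488), LIPE +0.16 (SE 0.227), PPARG +0.13 (SE 0.161) and PNPLA2 +0.12 (SE 0.145). Without castrated male 5 ANGPTL7 passed at -2.40 (adjusted p = 0.0153), and without female 1 a locus with no symbol passed. ADAMTS8 and COL28A1 were highest in female 2, at 18.2 and 18.5 CPM.

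With age, 5 lists of energy metabolism rose and 6 lists of immune, matrix, smooth muscle and nerve genes fell, by the preset correlation alone. Oxidative phosphorylation rose with all 14 members above 0 and a median slope of 0.20 per 10 days (adjusted p = 1.54e-05; adjusted p = 0.475 with an estimated correlation), with NDUFB5, a subunit of complex I, at +0.27 and SDHC, a subunit of complex II, at +0.28. Triglyceride assembly rose with 7 of 8 above 0 (adjusted p = 0.0138; adjusted p = 0.475 with an estimated correlation), CIDEC, a lipid droplet protein, at +0.48 and GPAM, the first enzyme of glycerolipid synthesis, at +0.20, against PCK1 at -0.67. Fatty acid oxidation rose with 13 of 16 above 0 (adjusted p = 0.0231; adjusted p = 0.475 with an estimated correlation), HADHA at +0.23 among them and CPT1A at -0.24. Fatty acid synthesis rose with 12 of 14 above 0 (adjusted p = 0.0252; adjusted p = 0.644 with an estimated correlation), the exceptions being the desaturases FADS1 and FADS2 at -0.22 and -0.34. Insulin signalling and glucose handling rose with 9 of 12 above 0 (adjusted p = 0.0301; adjusted p = 0.475 with an estimated correlation), SLC2A4, the insulin-responsive glucose transporter, at +0.42 among them. No member of these lists passed adjusted over the list alone.

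Macrophage markers fell with age with all 11 members below 0 and a median slope of -0.66 (adjusted p = 0.00120; adjusted p = 0.475 with an estimated correlation), C1QA at -0.91 (SE 0.373) among them. Inflammatory cytokines fell with all 12 below 0 (adjusted p = 0.00248; adjusted p = 0.475 with an estimated correlation), and CCL2, a monocyte chemoattractant, fell by 1.25 per 10 days (SE 0.311, p = 0.00736 adjusted over the list alone, 0 members past over all genes). T and NK cell markers fell with 11 of 14 below 0 (adjusted p = 0.0256; adjusted p = 0.644 with an estimated correlation). The fibroblast and matrix list fell with 14 of 16 below 0 (adjusted p = 0.0115; adjusted p = 0.475 with an estimated correlation), with fibronectin FN1 at -0.60, elastin ELN at -1.13 and the collagen cross-linker LOX at -0.78. Smooth muscle and pericyte markers fell with 6 of 8 below 0 (adjusted p = 0.0314; adjusted p = 0.475 with an estimated correlation), MYLK at -0.35 among them. Nerve and Schwann cell markers fell with 5 of 6 below 0 (adjusted p = 0.0498; adjusted p = 0.475 with an estimated correlation), and the adhesion gene NCAM1 fell by 0.36 per 10 days, adjusted over the list alone, with 0 members past over all genes. With an estimated correlation 0 of 27 lists passed (1 at an unadjusted p under 0.05), and with fry 0 (3 at an unadjusted p under 0.05). The other 16 lists did not pass with the preset correlation (adjusted p from 0.0803 to 0.796). Mitochondrially encoded genes were among them with all 8 members below 0 (0.470), opposite in sign to the nuclear genes of the same pathway, as were lipolysis (0.288), fatty acid uptake (0.796), MHC class II (0.339) and interferon-stimulated genes (0.339).

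Age calls of the metabolic and smaller lists leaned on single libraries. Leaving out 1 library ended the call for fatty acid synthesis in 7 of 20 fits, with the highest adjusted p, 0.283, without female 2. The call ended for T and NK cell markers in 8 fits (up to 0.378, without castrated male 5), smooth muscle markers in 8 (0.240, female 2), nerve markers in 14 (0.397, female 2), insulin signalling in 5 (0.157, female 6), fatty acid oxidation in 3 (0.144, female 3), the matrix list in 1 (0.120, castrated male 2) and cytokines in 1 (0.103, female 2). Oxidative phosphorylation, macrophage and triglyceride assembly lists passed in all 20. Without the libraries numbered 10 the count fell from 11 lists to 6, oxidative phosphorylation (adjusted p = 4.76e-07), triglyceride assembly (0.0272), macrophage markers (0.00354), cytokines (0.00354), the matrix list (0.0115) and cell proliferation (0.0272, falling), each with an adjusted p of 0.643 with an estimated correlation.

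The age slope was compared between the sexes as an interaction. In edgeR 0 loci passed, with 1170 at an unadjusted p under 0.05, limma-voom with quality weights called 0, and DESeq2 called 3 loci without symbols, 1 of them a locus of the sex-separating set. On simulated data, where the changes followed every label, the test recovered 19.4% of planted slope differences of a log2 of 1 per 10 days and 65.2% of those of 2.

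Isoforms of sex-separating loci differed between the sexes as labelled. Of 33316 isoforms, 8 were higher in females and 12 higher in castrated males, 20 in all and all from loci without a symbol. An isoform of XLOC_042132 stood at 37.4 ± 15.7 FPKM in females and 2.80 ± 8.80 FPKM in castrated males (SD, n = 10 each, log2 difference 6.85, adjusted p = 0.0261). An isoform of XLOC_042813 stood at 0.0887 ± 0.259 against 1.67 ± 0.810 FPKM (log2 difference -3.39, adjusted p = 0.0261). Without the libraries numbered 10 the count was 25 (11 higher and 14 higher in castrated males), among them an isoform of HYCC1 at +2.57 (adjusted p = 0.0159). Leaving out 1 library other than those numbered 10 left 0 isoforms, with 628 to 901 at an unadjusted p under 0.05.

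Isoform shares, the part of a locus's FPKM that 1 isoform takes, gave 0 differences of 18417 tested by limma, with 349 at an unadjusted p under 0.05 and 352 on the raw share, where 0 passed as well. Without the libraries numbered 10 the count was 0 again, with 409 at an unadjusted p under 0.05. The shares of smallest p belonged to TBX2, a T-box factor, at 29.3 ± 6.22% in females against 18 ± 5.89% in castrated males, MAPRE2, a microtubule end-binding protein, at 63.7 ± 7.99% against 75.5 ± 6.01%, and TBC1D1, a regulator of glucose transporter traffic, at 84.3 ± 4.94% against 92.8 ± 5.19% (SD, n = 10 each, adjusted p = 1 each). Planted differences of 0.2 on the arcsine square root scale were recovered in 61 of 100 simulated isoforms, and those of 0.1 in 14 of 100. These changes followed the label of every library.

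Genes of the same list rose and fell together from animal to animal for 18 of 27 lists. The mean pairwise correlation of members was 0.873 for mitochondrially encoded genes, 0.786 for nuclear oxidative phosphorylation genes, 0.752 for macrophage markers, 0.744 for MHC class II, 0.498 for fatty acid synthesis, 0.489 for T and NK cell markers, 0.487 for proliferation, 0.453 for interferon-stimulated genes, 0.395 for immediate early and heat shock genes and 0.389 for endothelial markers. Lists of fat storage and breakdown stayed under the bound set by their random lists. Triglyceride assembly had 0.148 against a bound of 0.205, lipolysis 0.178 against 0.194 and fatty acid uptake 0.117 against 0.151. They still exceeded most of their random lists, at percentiles of 92.26, 96.54 and 94.21. The lists of adipokines (0.118), steroid hormone genes (0.099), estrogen-responsive genes (0.047), X-linked genes (0.071), the clock (0.098) and brown or beige fat (-0.067) also stayed under their bounds. The count was 15 on FPKM, 19 by Spearman correlation and 20 without the libraries numbered 10.

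**Figure D4:**
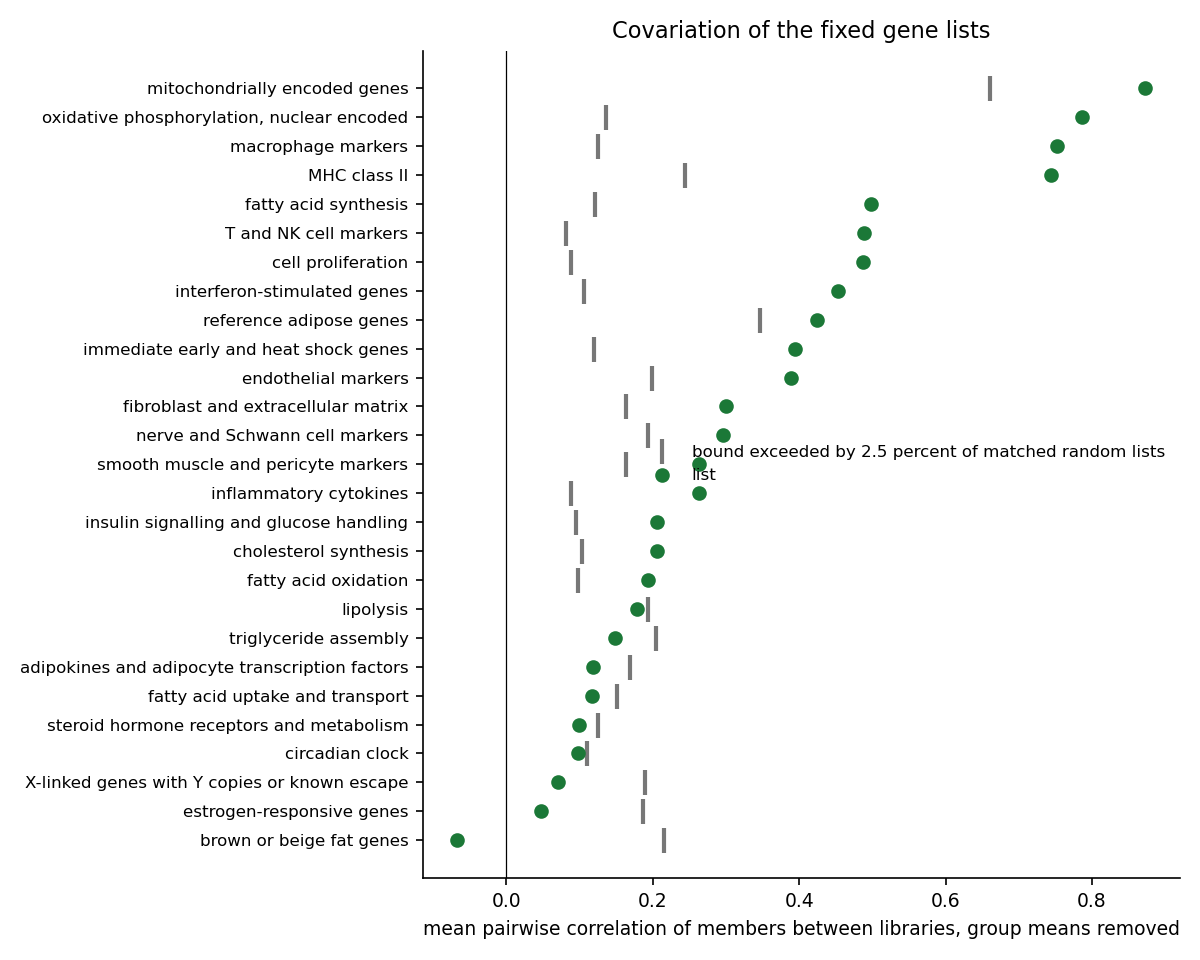
Mean pairwise correlation of the members of each list over 20 libraries with sex means removed (dots) and the bound that 2.5% of matched random lists exceed (bars). Mitochondrially encoded genes lie highest at 0.873 against a bound of 0.661, and fatty acid synthesis lies at 0.498.

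Animals with more fatty acid synthesis transcripts had more transcripts of nuclear-encoded oxidative phosphorylation genes and insulin signalling and fewer of endothelial markers. Over 20 animals the fatty acid synthesis score correlated with the insulin signalling score at r = 0.791 and rho = 0.750 (permutation p = 6e-05 and 0.00021, adjusted 0.00078 and 0.00546 over 26 correlations), and with r = 0.738 in females and 0.852 in castrated males. With oxidative phosphorylation r was 0.807 and rho 0.570 (permutation p = 5e-05 and 0.010, adjusted 0.00078 and 0.107), with r = 0.737 in females and 0.884 in castrated males. With endothelial markers r was -0.649 and rho -0.556 (permutation p = 0.00176 and 0.0124, adjusted 0.0153 and 0.107). On log2(FPKM + 1) the adjusted p of r was 0.0026 for insulin signalling and for oxidative phosphorylation, and 0.0595 for endothelial markers, which did not pass there. Without the 2 animals farthest from the median score, castrated male 1 (-1.85) and female 9 (-1.25), r was 0.617, 0.602 and -0.420.

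Steroid hormone genes (r = 0.591, rho = 0.495, permutation p = 0.00686 and 0.0279, adjusted 0.0446 and 0.122) and triglyceride assembly (r = 0.574, rho = 0.423, permutation p = 0.00916 and 0.0638, adjusted 0.0476 and 0.193) rested more on those animals, with r of 0.325 and 0.294 without them. Neither passed on log2(FPKM + 1) (adjusted p = 0.143 and 0.0629) or without the libraries numbered 10 (adjusted p = 0.078 each). The lipolysis score, with r = -0.136 and rho = -0.295 (permutation p = 0.566 and 0.207), and the macrophage score, with r = -0.259 and rho = -0.041 (permutation p = 0.270 and 0.866), gave no correlation that passed. The score of mitochondrially encoded genes gave none either, unlike that of nuclear oxidative phosphorylation genes (r = 0.262, rho = 0.062, permutation p = 0.265 and 0.797).

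**Figure D5:**
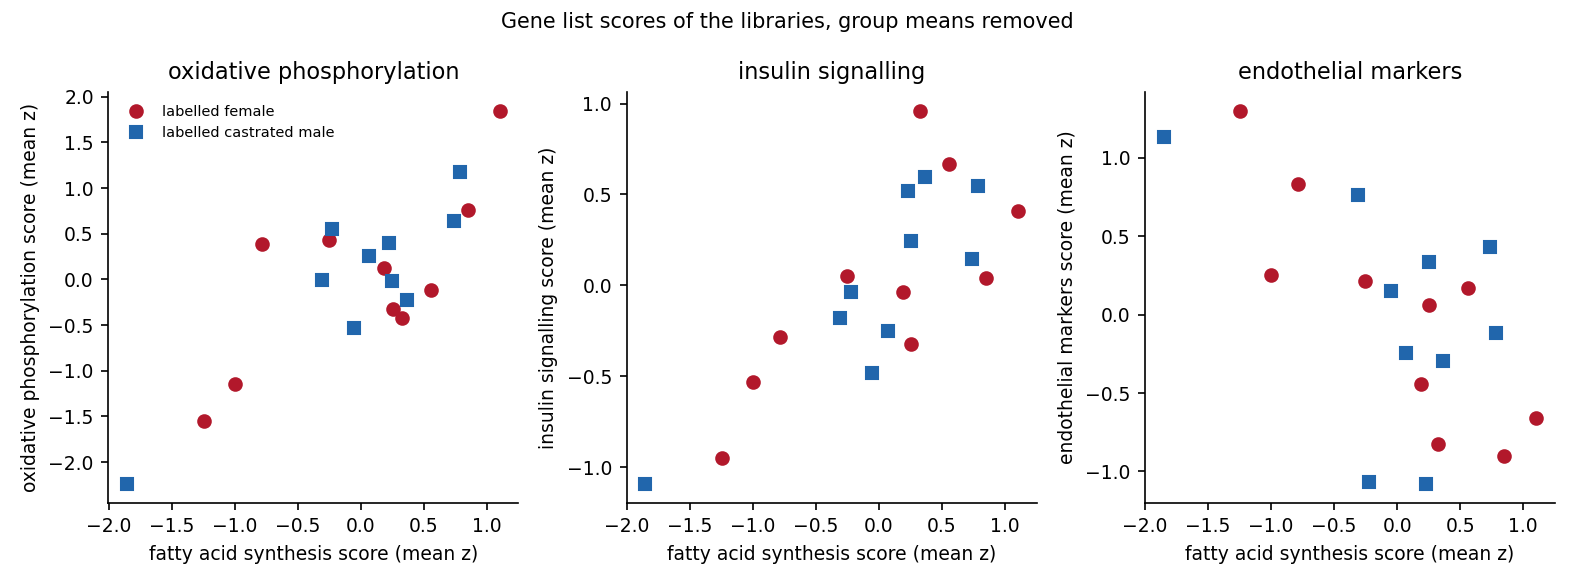
Scores of oxidative phosphorylation, insulin signalling and endothelial markers against the fatty acid synthesis score, each the mean z-score of list members with sex means removed, 1 point per library by labelled sex. Castrated male 1 lies at the far left of each panel at -1.85, and r is 0.807, 0.791 and -0.649 over all 20.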

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

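Tests in this part were chosen after the result was seen, except the permutation of the T and NK cell list alone and the partial correlation given depth. A library was singled out where its gap to the nearest of the others in its sex was large against the range of the 10, a rule that chance meets in about 1 of 20 groups. Of 114 groups tested, 19 values met it, 6 of them in castrated male 1 and 8 in the libraries numbered 10. XLOC_042132 and XLOC_042813 were entered after their values were seen, and flagged lists and genes of castrated male 1 share members. The tally therefore cannot be set against that rate.

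The libraries labelled female 10 and castrated male 10 stood apart from their labelled sex at most of the loci that separate the other animals. Scaled over all 20 libraries, XLOC_042132 was at 0.409 CPM in the library labelled female 10 and 989 CPM in the library labelled castrated male 10, XLOC_042813 at 314 and 0 CPM, and KDM6A at 40.5 and 63.5 CPM. An exchange of labels or samples between these animals is a candidate explanation: both lay on the other sex's side at 15 of the 18 loci found without them. Mixed RNA of both sexes was argued against, since at the loci of largest difference the libraries kept at most 0.560% of the mean of their labelled sex. An exchange in the count table alone was argued against as well, since the counts of all 20 libraries correlated best with their own FPKM column. By the labels these animals carry neighbouring numbers, set apart from the run of the other animals, which by itself decides nothing. An animal whose sex chromosomes differ from its recorded sex stays open as an untested biological explanation, as does an exchange with animals outside the series.

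Castrated male 1 had the lowest fatty acid synthesis and nuclear-encoded oxidative phosphorylation transcripts and the highest MHC class II of its sex. Its mean log2 CPM was 6.02 for fatty acid synthesis (median of the 10, 7.84), 6.46 for oxidative phosphorylation (7.21), 7.92 for the reference adipose genes (10.4) and 6.90 for MHC class II (5.62), with SCD at 253 CPM and PPARG at 149 CPM. For the rise of oxidative phosphorylation with fatty acid synthesis over the animals, a few libraries as the whole cause were argued against: r was 0.602 without castrated male 1 and female 9 (permutation p = 0.00843). A varying share of fat cells would move the markers of all other cell types alike. The fibroblast score went up with fatty acid synthesis (r = 0.531, adjusted p = 0.0687 over 26 permutation tests, bootstrap interval 0.191 to 0.747). Its r was at least 0.407 with any 1 library left out, and 0.374 without castrated male 1 and female 9. The endothelial score went down (r = -0.649, interval -0.854 to -0.217). Opposite signs are not what such a share alone predicts. The fibroblast correlation did not pass in that setting, however, and its list also holds matrix genes. With age removed as well as sex the correlation passed (r = 0.654, adjusted permutation p = 0.0157). It did not on log2(FPKM + 1) (adjusted p = 0.0874) or without the libraries numbered 10 (adjusted p = 0.078). A varying share of fat cells as the whole cause therefore stays undecided. The MHC class II (r = -0.425), smooth muscle (-0.400), nerve (-0.364) and macrophage (-0.259) scores lay on the side such a share predicts, without passing. Without castrated male 1 and female 9 the smooth muscle (-0.507) and nerve (-0.549) scores stayed there, while MHC class II (0.259) and macrophage (0.091) turned. The T and NK cell score had r = 0.020 over all 20 libraries and 0.419 without those animals. A varying share of fat cells may contribute, but these mixed signs do not decide it. Library depth was argued against, with a partial correlation of 0.788 given the total count (permutation p = 3e-05). Differences in feeding before slaughter or in fatness may contribute and were not tested, since the labels give neither.

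Lower immune lists in females were weighed as the pattern a biologist might follow first. Without castrated male 1 the macrophage and T and NK cell lists kept their calls with the preset correlation, at an adjusted p of at most 0.00126. With an estimated correlation neither list passed even over all libraries, so these calls cannot decide whether castrated male 1 alone was the cause. Without it the mean log2 CPM still differed by -0.428 for the T and NK cell list, against -0.498 with it. For the macrophage list the difference was -0.411 without it, against -0.610 with it. Castrated male 1 could account for the MHC class II call, whose adjusted p without it was 0.208. The interferon call ended without it as well, but also without other single libraries. Among these was the library labelled castrated male 10, with the highest mean log2 CPM of that list, 6.62 against 6.37 in castrated male 1. Chance stays open: the mean log2 CPM of the T and NK cell list differed by -0.498 with a permutation p = 0.0276 and that of the macrophage list by -0.610 with p = 0.109 in a permutation test, but the T and NK cell list had the largest difference of 27 lists relative to the spread within sex, and with that choice allowed for the permutation p was 0.402. Sex or castration stays among the open explanations and cannot be told apart from chance for these lists, since the T and NK cell difference stood out alone and not once the choice among the lists was allowed for.

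Counts of calls were set against 100 splits of the libraries, the real one included. With a real count of 0, as for genes between the sexes (highest other 2) and isoform shares (highest other 56), all 100 splits give as many by design, so they decide nothing. For the gene lists chance could not be excluded (8 real, 29 splits with as many, highest other 15). The other splits had a median of 5 lists, and 97 of them called at least 1 list with the preset correlation. For isoforms the count argued against chance, with 20 real, 1 split with as many, the real one, and a highest other of 8. It was not adjusted for the several counts compared here, so it does not exclude chance. The real count was 0 when any 1 library other than those numbered 10 was left out. Without the libraries numbered 10, 2 splits gave as many genes (18 real, highest other 387) and 2 as many isoforms (25 real, highest other 151). Those libraries were left out because of their values, a choice the other splits did not have, so these counts do not settle whether chance is excluded. For the lists it was not (8 real, 20 with as many, highest other 14). With ages permuted within sex, the counts for genes (0 real, highest other 82) and slope differences (0 real, highest other 5) decide nothing either. For the lists, 4 of 100 permutations, the real ages included, gave as many (11 real, highest other 12). The other permutations had a median of 5 lists, and 89 of them called at least 1 list. No allowance was made for the number of counts compared, so chance stays open for the real count of 11 lists. That count leaned on single libraries: it was 6 without female 6, the library labelled female 10 or castrated male 3, 7 without female 2, 6 without both libraries numbered 10, and 0 with an estimated correlation. The splits that gave 387 genes, 151 isoforms, 56 shares and, with ages permuted, 82 genes were the highest of their kind, against medians of 0. They may reflect a structure of the samples other than sex or age, or chance, and this was not tested.

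Other values far from their group are given without explanation. The library labelled castrated male 10 had the lowest mean log2 CPM of the lipolysis list, 6.23 against a median of 6.89, and PNPLA2 at 274 CPM against 610 CPM. Female 7 had CUX2 at 17.6 CPM against a median of 8.14 CPM. Castrated male 7 had SLITRK6 at 6.06 CPM against 21.8 CPM. Female 2 had ADAMTS8 at 18.2 CPM against 2.84 CPM and COL28A1 at 18.5 CPM against 3.13 CPM. Castrated male 9 had COL28A1 at 10.3 CPM against 2.33 CPM.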

How the results depend on the processing

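The fits without the libraries numbered 10 were chosen after the data were seen, and all other alternatives before. Between the sexes, edgeR gave 0 genes with RLE and upper-quartile factors, no filter, the stricter filter, the 10 highest loci left out, muscle score or age added (515 to 1117 loci at an unadjusted p under 0.05), DESeq2 gave 5, limma-voom with quality weights 9, and FPKM 9 with a pseudocount of 1 and 11 with 0.1. Without the libraries numbered 10 it was 18, and 26 with DESeq2. Leaving out 1 library gave 0 to 13 genes: 13 without the library labelled female 10, 7 without the library labelled castrated male 10, and 0 otherwise. For age, DESeq2 gave 6 genes, FPKM 1 with either pseudocount, DESeq2 without the libraries numbered 10 gave 2, and leaving out 1 library gave 0 or 1. For the slope difference DESeq2 gave 3 and leaving out 1 library 0 or 1. The cause was not tested, apart from the libraries numbered 10.

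For gene lists between the sexes, an estimated correlation gave 0 of 27, fry 0, an estimated correlation without the libraries numbered 10 gave 0, age added gave 5, and leaving out 1 library 6 to 11. For age, an estimated correlation gave 0, fry 0, an estimated correlation without the libraries numbered 10 gave 0, leaving them out 6, and leaving out 1 library 6 to 13. Isoforms gave 14 to 26 under other filters and pseudocounts, 25 without the libraries numbered 10, and 0 to 24 with 1 library left out. Isoform shares gave 0 throughout. Covariation called 15 to 20 lists. Of 20 alternative values of the 5 called score correlations, 11 still passed and 9 did not, all with direction kept.

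Sex differences of adipose genes near 0 turned sign, all far from passing, and the cause was not tested. PPARG was 0.001 with upper-quartile factors. FASN was -0.124 with age added, -0.053 without the libraries numbered 10 and -0.063 there with DESeq2. SCD was -0.174 with the muscle score added and -0.033 with age added. PNPLA2 was 0.002 with RLE, 0.026 with upper-quartile factors, 0.020 with the stricter filter and 0.005 without the 10 highest loci. With 1 library left out PPARG ran from -0.096 to 0.026, FASN from -0.082 to 0.277, SCD from -0.052 to 0.222, PNPLA2 from -0.085 to 0.044 and LIPE from -0.148 to 0.040. Over all named genes, 443 alternative values of the sex difference kept direction and side, 42 turned and 7 passed; for age 493 kept both and 0 turned.

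The sex chromosome test and its 2 alternatives were not run, since chromosomes were given for another genome build than that of the loci. Depth limits loci under 1 CPM, which rest on fewer than 51.2 counts per library. No paired analysis was possible because the library numbers pair no animals.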

Other observations

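These values belong to no comparison, and no test was planned for them. A few heat shock, immediate early and cartilage genes ranged widely between animals. The heat shock genes HSPH1 and DNAJB1 reached 3237 and 1577 CPM in female 4, against medians over the 20 libraries of 271 and 177 CPM, and HSP90AA1 reached 3910 CPM in female 7 against a median of 947 CPM. FOS, an immediate early gene, ran from 710.4 CPM in female 7 to 3753 CPM in female 9. COMP, a cartilage matrix protein, ran from 0.409 CPM in the library labelled female 10 to 124 CPM in female 1, and CILP2 was highest in female 1 as well, with castrated male 7 close to it. SPP1, the matrix protein osteopontin made by activated macrophages, reached 738 CPM and MMP9, a gelatinase of neutrophils and macrophages, 68.1 CPM in castrated male 8, against medians of 81.3 and 7.30 CPM.

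HBB and CA3 varied between animals as well. HBB, a hemoglobin chain, ran from 18.7 CPM in female 1 to 732 CPM in castrated male 8, and CA3, a carbonic anhydrase of muscle and fat cells, from 202 CPM in castrated male 1 to 2892 CPM in female 7. Markers of B cells, neutrophils and mast cells, skeletal muscle, red blood cells, skin, glands and the Y chromosome had 0 to 4 tested members per list, too few for a list test.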
